A study of Mus musculus with 6 samples.

How the data were processed

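Total RNA from 6 samples was amplified by a modified Eberwine protocol into biotin-labelled cRNA and hybridised to 1-colour CodeLink Mouse Whole Genome arrays, per the labels' protocols. Each array gave 34967 spots for mouse transcripts besides its control spots. Per the file headers, the spots were quantified with CodeLink Expression Analysis 4.1, which reports a raw intensity, a normalized intensity and a quality flag for each spot. The raw intensity in the deposited files was already corrected for local background, since 38 to 67 spots per array were below 0. The normalized intensity is the raw intensity divided by the median of the array's transcript spots, per the file headers. The authors' value table holds that normalized intensity times a single factor per array, 1.01 to 1.02 as measured here, with missing and negative spots set to 0. Its column medians were 1.009 for null sample 6, 1.008 for wild-type sample 7, 1.003 for null sample 9, 1.009 for wild-type sample 10, 1.004 for null sample 11 and 1.006 for wild-type sample 12. Its scale is therefore linear and it is not centred by gene. The quality flags mark good, near-background, irregular, contaminated, saturated and defective spots. The deposited summary files of the control spots were not used, and the negative control medians were taken from the spots in the array files. Apart from the RefSeq table, no genome build is named in the sources used here.

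Samples were assigned to genotype by the labels, 3 Fkbp8 null and 3 wild type. The sample numbers are not shared between the groups, so the samples were not paired. All arrays were quantified in a single session per the file headers, so no batch could be tested. Raw intensities were floored at 0, an offset of 50 was added, and log2 values were quantile normalized over the transcript spots. This is the form the design named for values that already are background-subtracted. Spots flagged irregular, contaminated or defective (391 to 543 per array) were left out, and saturated spots were kept. A probe was tested where it was above the near-background flag on all arrays of at least 1 group and had at least 2 usable values in each group, which left 21243 probes, 14690 of them named, for 12850 genes. Differences are null minus wild type on the log2 scale, and the offset compresses those of dim probes. They were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all probes tested at a threshold of 0.05. Where a gene was near background on every array of a group, the fold is a lower bound. It sets the bright group's mean against the higher of the dim probe's own signal and the lowest signal above background on each array.

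Gene names came from a table of the platform annotation, which gave 1 symbol for 21615 spots, several for 681 and none for 12671. Symbols were looked up by Entrez gene number in the RefSeq table for GRCm38.p6, with 21487 matches. Of the spots without a listed symbol, 499 were named through their RefSeq accession. In total 12853 spots stayed unnamed here, including those with several symbols. The annotation's accession equalled the one in the array file for 78.0% of the 22296 spots listed. The GRCm38.p6 table was otherwise used only to tell which genes neighbour each other, and no coordinates are given.

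The design, the alternatives and 38 gene lists for tissues, pathways and cell states were fixed before the data were examined. List tests used 1 probe per gene, that with the highest mean signal. They ran camera of limma with a preset correlation between genes of 0.01, over 12190 genes measured on all 6 arrays, with adjustment over the 36 lists that had at least 5 measured members. Of these, 7 passed, 3 higher and 4 lower. None passed with an estimated correlation (smallest adjusted p = 0.543) or with fry (smallest adjusted p = 0.494), which tests whether the genes of a list move on balance in a single direction. Counts adjusted over the list alone used the limma p of the members and were not adjusted for the number of lists. The lists of hedgehog response and ventral neural tube share Nkx6-1, Foxa2 and Nkx2-9.

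Genes to be named were taken by a rule. Fkbp8, Ptch1, Gli1, Foxa2, Nkx2-2, Pax6 and Pax7 were named whatever their values. Among probes with a single symbol and no overlap between the groups, those past the threshold with the largest change were named in each direction, filled up to 10 by the smallest p where under 5 passed. Within a list the members with the smallest p could be named, at most 3 for the main lists and 2 for the others. Other genes named in the text (Shh, Olig2, Spon1, Slit1, Hhip, Pax3, Krt5, Krt14, Epcam, Stk38l, Foxc2, Cdx2, Vangl2, Grhl3, Xist, Eif2s3y and the neighbours of Fkbp8) were chosen after their values were seen.

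Genes within 10 Mb of Fkbp8 were compared with all other placed genes by Fisher's exact test, two-sided, on the count with an unadjusted p under 0.01. The alternatives covered the offset, the background floor, median scaling and cyclic loess, the scanner software's normalized intensity, the authors' value table, the filter on dim probes, the quality flags, the variance model, array weights, 1 probe per gene, a threshold of 0.10, the removal of Xist and Y-linked probes, and leaving out each array in turn. Figures were drawn with matplotlib.

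The code was tested on simulated arrays with the means and spreads of these probes. For the comparison of null with wild type over 21243 probes, 200 probes were changed. At a log2 change of 1 limma recovered 76.0% of them with 10 false calls, at a log2 change of 2 it recovered 96.5% with 8 false calls, and with no change it made 0 calls. In 20 simulations over 12850 genes, a list of independent genes shifted by 0.3 on the log2 scale was found each time, with 0 other lists called. All simulated genes varied independently, so this does not measure false calls where the genes of a list vary together. On the real arrays, null samples 6 and 11 with wild-type sample 7 set against the rest gave 8 lists at the preset correlation.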

Results

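Gene expression was measured in the posterior part of mouse embryos at embryonic day 9.5, the stage at which the neural tube is still open at the posterior neuropore. The 6 samples were 3 from embryos without functional Fkbp8 (samples 6, 9 and 11) and 3 from wild-type embryos (samples 7, 10 and 12). The labels give the same average of 21.6 somite pairs for every sample, so a difference in stage between the groups could not be checked. Fkbp8 is a membrane-anchored immunophilin that binds Bcl-2, and it is known as a negative regulator of hedgehog signalling in the mouse neural tube. The stock was a mix of the C57BL/6 and 129S5 strains. According to the labels the embryo was severed just below the forelimb pit, so the tissue held neural tube together with somites, surface ectoderm, gut and blood. The tissue label names the posterior neural tube and the source label names the anterior neural tube. The dissection protocol and the series title both describe the posterior part, and that reading was used. Each array carried 34967 probes for mouse transcripts, of which 63.3% to 69.2% per array lay above background. The median spot intensity was 2.33 to 3.80 times that of the negative control spots. Nothing in the labels says whether each sample was a single embryo, so the p-values measure only the spread between these samples, and the number of arrays limits the precision.

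The first comparison checked the targeted gene in every sample. Fkbp8 was near background on all 3 null arrays, with background-subtracted intensities of 24.7, 28.9 and 35.7 in samples 6, 9 and 11. It was above background on all 3 wild-type arrays, with intensities of 123, 183 and 486 in samples 7, 10 and 12. The mean normalized log2 signal was 6.32 ± 0.10 in the null group and 8.09 ± 0.53 in the wild-type group (SD, n = 3 each), so the groups did not overlap, although this does not tell a heterozygous from a wild-type embryo. Because the null arrays give only an upper bound, Fkbp8 was at least 3.33-fold lower in them. The fitted log2 difference was -1.77 ± 0.23 (SE; -2.89 with subtraction floored at 1), with a limma adjusted p = 0.409 over all 21243 probes tested. Where the probe lies relative to the disrupted part of the gene is not given in the sources used here. Of the 13 measured members of the Fkbp family list, 10 were lower and 3 higher in the null arrays, and the family did not shift as a group (camera adjusted p = 0.287).

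The second comparison asked which transcripts differed between null and wild-type tissue. Tm7sf3, which encodes a membrane protein with 7 transmembrane segments, was the single probe past an adjusted p of 0.05. Its log2 signal rose from 6.19 ± 0.41 in wild type to 9.25 ± 0.07 in null tissue (SD, n = 3 each), a log2 difference of 3.06 ± 0.19 (SE; limma adjusted p = 0.00311), and the wild-type signal was above background on 1 of 3 arrays. Fgfr1op2, its neighbour in the GRCm38.p6 annotation, was above background on all 3 null arrays, with the irregular spot of sample 11 left out of the fit, and on no wild-type array. It was at least 2.43-fold higher in the null tissue, with a log2 difference of 1.40 ± 0.15 (SE; 2.79 with subtraction floored at 1) and an adjusted p of 0.240. No probe passed in the lower direction. At an unadjusted p under 0.05 limma counted 656 probes, 373 higher and 283 lower in the null arrays, which is 3.09% where 5% would arise by chance. Without wild-type sample 10 the count was 1355 (6.30%), without null sample 9 it was 394 (1.85%), and with median scaling 291 (1.37%). The 3 null values lay wholly above or below the 3 wild-type values for 9.25% of probes, where chance gives 10%. The call on Tm7sf3 was lost without null sample 6 (adjusted p = 0.0680) or without null sample 9 (0.0548), although its log2 difference stayed at 3.13 and 2.99. It was also lost with median scaling (log2 difference 3.08, adjusted p = 0.0537) and cyclic loess (3.08, 0.0765). With subtraction floored at 1 (5.13, 0.893), the scanner software's normalized intensity (4.74, 0.357) and the authors' value table (4.73, 0.366) the call was lost while the difference grew. Fgfr1op2 passed when every spot was kept whatever its flag (0.0380).

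The remaining probes with the smallest p among those without overlap are given as values, since none passed the adjusted threshold (adjusted p = 0.9999 for each). On the higher side, Gatad2a, a subunit of the NuRD complex whose gene neighbours Fkbp8, had a log2 difference of 0.53 ± 0.10 on this probe and 0.04 on its brighter probe. Timp3, an inhibitor of matrix metalloproteinases, had 0.59 ± 0.14, Prss12 0.48 ± 0.10, Trrap 0.47 ± 0.11 (0.16 on its other probe), and the near-background Akr1d1 was at least 1.17-fold higher. On the lower side, Gngt2 had -0.63 ± 0.15, the netrin receptor gene Unc5a -0.48 ± 0.11, Mt2 -0.44 ± 0.12, S100a11 -0.42 ± 0.12, Ccnt1 -0.41 ± 0.12 (0.07 on its other probe), Kcnk3 -0.41 ± 0.12, Spns2 -0.40 ± 0.11 and Il5 -0.35 ± 0.10. Nrip3, near background in the null arrays, was at least 1.24-fold lower. With subtraction floored at 1 the differences of dim genes were larger, at 0.72 for Prss12, -1.03 for Unc5a and -0.93 for Kcnk3, and that of Mt2 was -0.67 with the authors' value table.

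Several genes that respond to hedgehog signalling or mark the ventral neural tube had a higher mean signal in the null arrays. The shift of either list as a group passed camera at its preset correlation only (adjusted p = 0.610 with an estimated correlation and 0.494 with fry, for both). Of the 11 measured hedgehog response genes, 7 were higher and 4 lower, and 4 passed when adjusted over the list alone, all of them higher: Ptch1, Nkx6-1, Foxa2 and Nkx2-9. Ptch1, which encodes the hedgehog receptor and is itself a target of the pathway, had a log2 difference of 0.67 ± 0.13 (SE). The ventral progenitor transcription factor Nkx6-1 had 0.83 ± 0.17, the floor plate factor Foxa2 0.72 ± 0.17 and the ventral factor Nkx2-9 0.73 ± 0.19. Of the 9 measured ventral neural tube genes, 6 were higher and 5 passed over the list alone: Nkx6-1, Foxa2 and Nkx2-9 again, with the floor plate product Spon1 at 0.61 ± 0.19 and Slit1 at 0.39 ± 0.14. Without wild-type sample 7 or without null sample 9 only 3 passed, with Spon1 and Slit1 lost. With subtraction floored at 1 the difference of Nkx2-9 was 1.11. None of these genes passed over all probes tested (adjusted p = 0.9999 for each). The adjustment over a list alone makes no allowance for the 38 lists, and no member of any other list passed it. Gli1, a direct transcriptional target of the pathway, had a log2 difference of -0.07 ± 0.13 (-0.18 without wild-type sample 10), and Hhip, which lies within 10 Mb of Fkbp8, had 0.31 ± 0.12. A second and dimmer Ptch1 probe gave -0.02. At the preset correlation the camera adjusted p was 0.00101 for each list. Without wild-type sample 10 the hedgehog response list no longer passed (adjusted p = 0.0930), while the ventral list did (9.89e-04). Shh and Olig2 were near background on all arrays and Nkx2-2 was above it on only 1 of 3 arrays in each group, so these genes were not tested. The 18 measured components of the hedgehog pathway itself, from receptors to ciliary genes, had a median log2 difference of 0.03 and did not shift (camera adjusted p = 0.786).

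**Figure D1:**
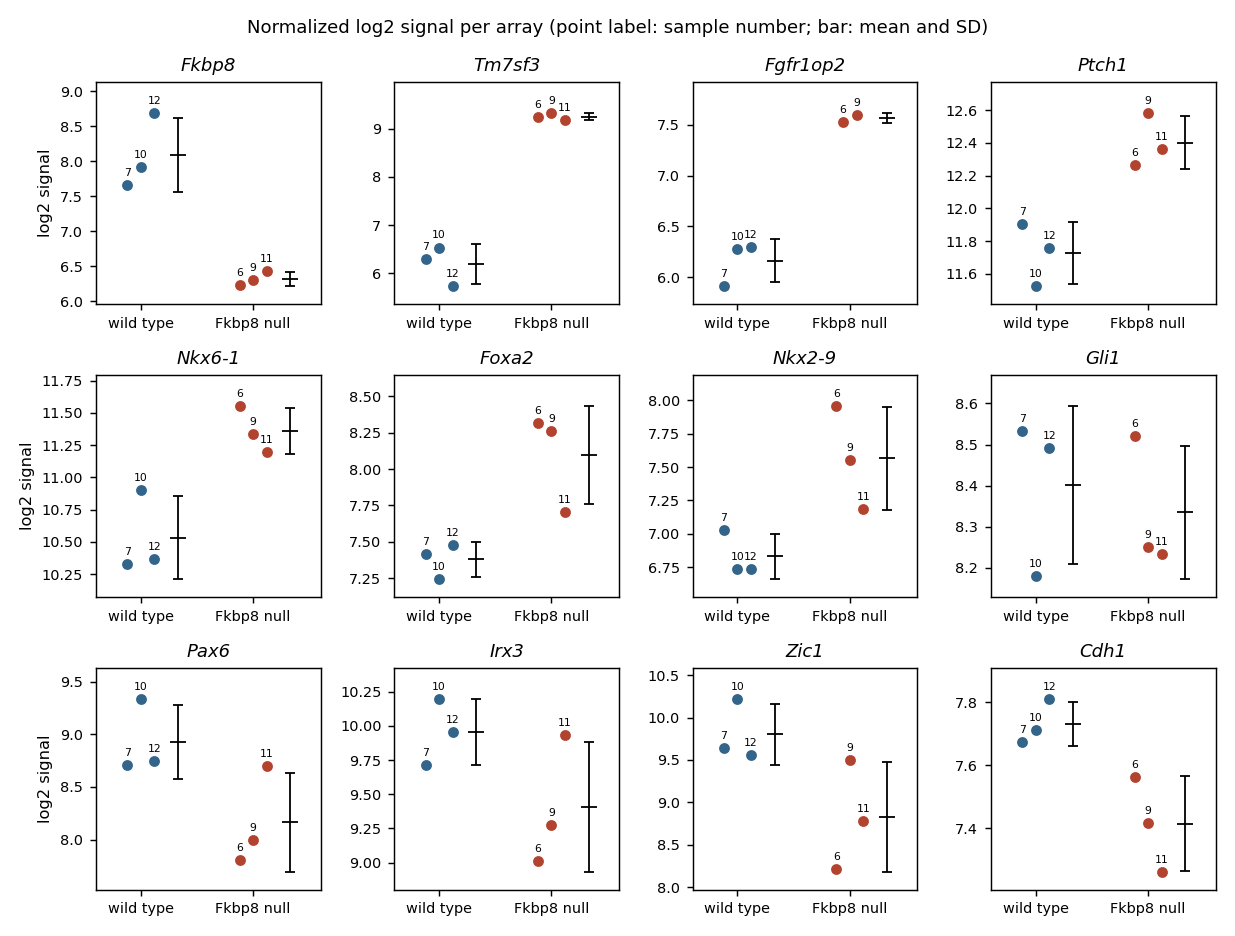
Normalized log2 signal (vertical axis) of 12 genes on each array, wild type in blue and Fkbp8 null in red, with the sample number beside each point and the mean and SD as a black bar; vertical axes differ between panels and do not start at 0. Fkbp8 lies at 6.23 to 6.42 on the null arrays and at 7.65 to 8.68 on the wild-type arrays, and Ptch1, Nkx6-1, Foxa2 and Nkx2-9 lie higher on each null array than on any wild-type array.

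All 7 measured genes of the intermediate neural tube had negative differences, with none past the list alone, and genes of the dorsal neural tube went both ways. Pax6, a transcription factor of intermediate and dorsal progenitors, had a log2 difference of -0.76 ± 0.25 (SE), Irx3 -0.55 ± 0.23 and Dbx1 -0.79 ± 0.45, of which Dbx1 moved to -0.25 without wild-type sample 10 and to -1.24 without wild-type sample 7, and Irx3 to -0.35 without null sample 6. The intermediate list passed camera at its preset correlation (adjusted p = 0.00108), but not with an estimated correlation (adjusted p = 0.610) or fry (0.968). Its array mean in null sample 11 (0.10) was above those of wild-type samples 7 (0.01) and 12 (0.03). Of the 15 dorsal genes, 10 were lower and 5 higher, and none passed over the list alone. Zic1 had -0.97 ± 0.31, the dorsal progenitor factor Olig3 -0.70 ± 0.26 (-0.43 without wild-type sample 10), Msx1 -0.29 ± 0.12 and Pax3 -0.03 ± 0.09. Against the other genes the dorsal list was placed lower (camera adjusted p = 0.00616; 0.610 as the adjusted p with an estimated correlation), with a mean of -0.16 and a median of only -0.03. Pax7 was near background on all arrays. Neural crest genes had the highest adjusted p among the lists that passed: 9 of 11 were lower, none passed over the list alone, the median was -0.06 and the camera adjusted p was 0.0449 (adjusted p = 0.610 with an estimated correlation). The crest specifier Foxd3 had a log2 difference of -0.16 ± 0.09 and the receptor gene Erbb3 -0.18 ± 0.11. The intermediate list was lost without wild-type sample 10 alone (adjusted p = 0.174). The dorsal list was lost without wild-type sample 10 (adjusted p = 0.520), wild-type sample 7 (0.106) or null sample 6 (0.101). The neural crest list was lost without wild-type sample 10 (adjusted p = 0.345), null sample 11 (0.244), null sample 6 (0.101) or wild-type sample 7 (0.0778), and without the filter on dim probes (0.218).

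All 14 measured surface ectoderm genes had negative differences. None passed over the list alone. The epithelial cadherin Cdh1 had a log2 difference of -0.32 ± 0.11 (SE), the claudin Cldn4 -0.34 ± 0.13, Epcam -0.25 ± 0.11 and the keratins Krt5 -0.65 ± 0.26 and Krt14 -0.21 ± 0.10. The list had a median of -0.24 and was placed lower by camera at its preset correlation (adjusted p = 2.01e-05). It did not pass with an estimated correlation (adjusted p = 0.543) or fry (0.494). The call at the preset correlation held whichever of the 6 arrays was left out, although Cldn4 moved to -0.22 without null sample 9 and Epcam to -0.15 without wild-type sample 12. Among 12 measured endoderm and yolk sac markers, which share Epcam with this list, 6 were lower and 6 higher, with Cldn7 at -0.33 ± 0.12, and the list did not pass (camera adjusted p = 0.757; 0.0193 without null sample 6).

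Of the 12 measured somite and sclerotome genes, 11 had positive differences and none passed over the list alone. The mesenchymal homeobox gene Meox2 had a log2 difference of 0.40 ± 0.17 (SE), and the sclerotome factor Pax9 0.35 ± 0.16. Without null sample 9, Meox2 moved to 0.23 and Pax9 to 0.17, and Pax9 was 0.68 with subtraction floored at 1. The list passed camera at its preset correlation (adjusted p = 0.00128), but not with an estimated correlation (adjusted p = 0.610) or fry (0.968). Without wild-type sample 10 its mean went from 0.31 to 0.14 and it did not pass (adjusted p = 0.174), and the array mean of null sample 11 (-0.02) lay below that of wild-type sample 12 (0.18).

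**Figure D2:**
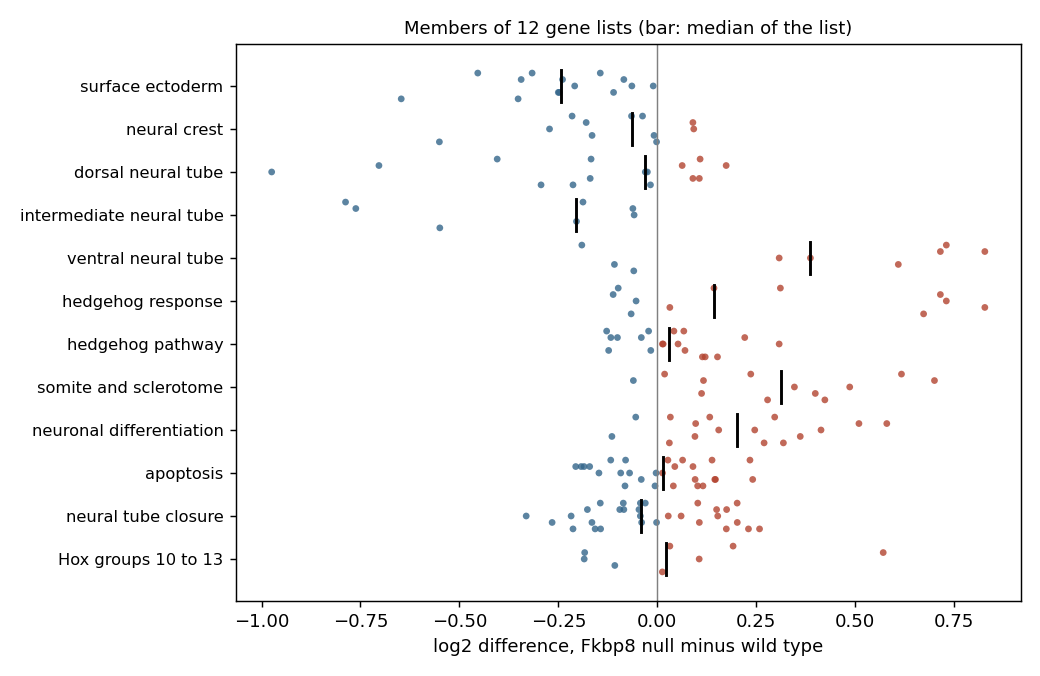
Log2 difference between Fkbp8 null and wild type (horizontal axis) of each measured member of 12 gene lists fixed before the data were examined, red above 0 and blue below 0, with the median of each list as a black bar; vertical position within a list carries no value. All 14 surface ectoderm genes and all 7 intermediate neural tube genes lie below 0, and 11 of 12 somite genes lie above 0.

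Over all probes tested, the wild-type arrays were less alike (mean Pearson correlation 0.978) than the null arrays (0.985) or pairs across the groups (0.983). Wild-type sample 10 correlated at 0.979 to 0.985 with the null samples, 0.977 with wild-type sample 7 and 0.975 with wild-type sample 12. Sample 10 differed from the other 5 arrays in several tissue markers. Its Foxc2 signal was 9.48 on the log2 scale, where the other arrays had 11.1 to 11.6, and its tail bud factor Cdx2 was 7.81 against 9.13 or more elsewhere. The mean of the tail bud and presomitic list, relative to the average over the arrays, was -0.65 on this array, and that of the somite list -0.49. The intermediate neural tube list was at 0.51 (-0.39 in null sample 6), the primitive erythroid list at 0.56 (-0.40 in null sample 6) and the neural progenitor list at 0.33. Sample 10 was also the single array with Xist clearly above background on its brighter probe (log2 signal 10.3 against 5.98 to 6.53 on the others). The dimmer Xist probe was near background on every array, with 6.17 in sample 10. Its Y-linked Eif2s3y signal was 6.16 where the others had 8.63 to 8.91. Eif2s3y was above background on all 3 null arrays and on 2 of the 3 wild-type arrays. By Xist and Eif2s3y, sample 10 had a female pattern and the other 5 samples a male one, so sex was not balanced between the groups. The 4 measured Y-linked genes were all higher in the null group, too few members for a list test. Given this imbalance, that cannot be read as an effect of genotype. Kdm5d had 0.46 ± 0.17, although its log2 signal in wild-type sample 12 (7.80) was close to that in sample 10 (7.77). Over all 6 arrays the tail bud and presomitic list did not shift (20 measured genes, camera adjusted p = 0.960), with Rspo3 at 0.37 ± 0.37 over all arrays and -0.06 without sample 10. Without sample 10 camera at its preset correlation placed the same list lower in the null arrays (adjusted p = 1.21e-04). The genes of this list varied together, with an estimated correlation of 0.578 and an adjusted p of 0.982 at that correlation over all 6 arrays. An estimated correlation was not tried without sample 10. The array mean of null sample 6 (0.16) was close to that of wild-type sample 12 (0.17).

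Genes of neuronal differentiation were higher in 14 of 16 measured members, with Nhlh2 at 0.51 ± 0.19, Ebf2 at 0.58 ± 0.25 and Neurog3 at 0.27 ± 0.10 (1.14 for Nhlh2 and 0.55 for Neurog3 with subtraction floored at 1), and the list just missed the threshold (camera adjusted p = 0.0671). It passed under 10 of the 16 alternative settings, with an adjusted p of 1.21e-04 without wild-type sample 10 but 0.811 without null sample 9, 0.640 without wild-type sample 7 and 0.561 without wild-type sample 12. The adjusted p was 0.891 with an estimated correlation and 0.973 with fry, and Nhlh2 and Ebf2 moved to 0.32 and 0.31 without null sample 9. Nhlh2 was 0.17 with every spot kept whatever its flag. Neural progenitor genes were lower in 9 of 12 members without passing (adjusted p = 0.163), with Nes at -0.17 ± 0.09, and passed without wild-type sample 7 (adjusted p = 0.0375). Head and brain markers, lower in 8 of 11, gave the same adjusted p, with Dlx2 at -0.23 ± 0.10, and passed without null sample 11 (adjusted p = 0.0371), without wild-type sample 12 (0.0469) and with cameraPR (0.0487).

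Apoptosis genes did not shift (27 measured, 14 higher and 13 lower, camera adjusted p = 0.902), with the pro-apoptotic genes Hrk at 0.24 ± 0.10 (0.49 with subtraction floored at 1) and Bmf at -0.19 ± 0.09, and the inhibitor Xiap at -0.21 ± 0.10 (-0.36 likewise). The p53 target list did not shift either (22 measured, adjusted p = 0.939), and its member with the smallest p was Ddit4 at 0.39 ± 0.12. Mouse genes required for neural tube closure went both ways, 12 higher and 18 lower (adjusted p = 0.803), with the Wnt co-receptor Lrp6 at 0.26 ± 0.11, the planar polarity genes Vangl1 at 0.23 ± 0.13 (0.35 without wild-type sample 12) and Vangl2 at -0.09 ± 0.11, and Grhl3 at -0.08 ± 0.11. None of these genes passed over its list alone.

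Axial identity did not differ detectably. The Hox genes of paralog groups 10 to 13 had a median log2 difference of 0.02 (camera adjusted p = 0.883) and, with an array left out, Hoxd11 ran from 0.37 to 0.76, Hoxb13 from -0.31 to -0.12 and Hoxa11 from -0.33 to 0.03. The central Hox genes had a median of -0.04 (adjusted p = 0.803) and the more anterior Hox genes 0.01 (0.960). Retinoic acid genes (adjusted p = 0.884), BMP response genes (0.899) and folate and 1-carbon metabolism genes (0.884) did not shift, with the BMP antagonist Grem1 at 0.30 ± 0.09 (0.46 with subtraction floored at 1) and Mthfd2 at 0.25 ± 0.10.

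Among cell state lists, mitophagy and mitochondrial dynamics, processes in which Fkbp8 takes part as an LC3-binding receptor, did not shift (13 of 17 members higher, camera adjusted p = 0.665), with the fusion gene Opa1 at 0.20 ± 0.09. Oxidative phosphorylation (adjusted p = 0.372), hypoxia response (0.757), unfolded protein response (0.803), cell cycle (0.757), ribosomal protein (0.803) and immediate early genes (0.803) did not pass. The ribosomal protein list passed with cyclic loess (adjusted p = 0.0182) and the hypoxia list without wild-type sample 12 (0.0358). Markers of other tissues likewise did not pass. The adjusted p was 0.112 for primitive erythroid, 0.428 for intermediate mesoderm, 0.786 for heart, 0.786 for limb and lateral plate, 0.803 for germ cell and 0.960 for endothelial genes, and only 4 macrophage genes were measured, too few to test. The primitive erythroid list passed without null sample 9 (adjusted p = 4.74e-04), without wild-type sample 7 (0.00176), without wild-type sample 12 (0.0469) and with cameraPR (0.0487), each at the preset correlation. Over all 6 arrays its adjusted p was 0.891 with an estimated correlation and 0.973 with fry. Without wild-type sample 10 it changed direction (camera adjusted p = 0.725). For the limb, endoderm, germ cell, apoptosis and anterior Hox lists the median was above 0 while camera placed the list below the other genes, so these lists have no clear direction.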

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

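The alternatives were fixed before the data were examined, except cameraPR over genes with a missing spot and all those of the test around Fkbp8, which were chosen after seeing the data. No paired analysis was possible because the 2 groups share no sample numbers. Signal over background limits the comparison most where a gene lies near background in a group, as Fkbp8 does in the null arrays.

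The log2 difference of Fkbp8 kept its sign and stayed short of the threshold under all 15 alternatives run, from -2.89 with the authors' value table to -1.41 without wild-type sample 12. The count of probes past the threshold was 1. It was 0 with plain subtraction floored at 1, median scaling, cyclic loess, the scanner software's normalized intensity, the authors' value table and the filter to probes above background on all 6 arrays, and 2 (Tm7sf3 and Fgfr1op2) with every spot kept whatever its flag. It ranged from 0 to 1 with an array left out, and was 0 without null sample 6 or null sample 9. The probes at an unadjusted p under 0.05 numbered 291 with median scaling and 1355 without wild-type sample 10. The cause was not tested.

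The number of lists past the threshold was 7. It was 0 with camera at an estimated correlation and 0 with fry, and between 4 (without wild-type sample 10) and 10 (without wild-type sample 12) with an array left out. With an estimated correlation the adjusted p was 0.543 for surface ectoderm and 0.610 for the other 6 called lists. With fry it was 0.494 for surface ectoderm, hedgehog response and ventral neural tube, 0.968 for intermediate neural tube and somite, 0.973 for dorsal neural tube and 0.831 for neural crest. Fry and the estimated correlation allow for genes of a list that vary together. The neural crest list was also lost with an offset of 16 (adjusted p = 0.0567), floored subtraction (0.0737), scanner intensity (0.0625), the value table (0.0631) and no filter on dim probes (0.218). With an array left out the adjusted p ran from 1.39e-04 to 0.0930 for hedgehog response, 1.53e-05 to 0.174 for intermediate, 8.77e-05 to 0.520 for dorsal, 1.56e-05 to 0.174 for somite and 0.00724 to 0.345 for neural crest, the highest each time without wild-type sample 10. Ptch1, Nkx6-1, Foxa2 and Nkx2-9 passed over the hedgehog response list alone in each of the 13 alternatives run for that count, while the ventral list's 5 members became 3 without wild-type sample 7 or null sample 9.

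Lists that had not passed changed direction under some settings, mostly with an adjusted p far from the threshold. Without the filter on dim probes this held for BMP response (0.880), endoderm (0.914), anterior Hox (0.968) and tail bud (0.914), and with fry for apoptosis and anterior Hox (0.973 each). With cameraPR it held for anterior Hox (0.999) and limb (0.890). For endothelial genes it held with median scaling (0.979), loess (0.958), scanner intensity and the value table (0.983 each), and for p53 targets with median scaling (0.986), scanner intensity and the value table (0.983 each). With an array left out, the lists that turned at least once ranged as follows in adjusted p. Tail bud ran from 1.21e-04 to 0.993, endoderm from 0.0193 to 0.993, hypoxia from 0.0358 to 0.993, neural progenitor from 0.0375 to 0.844, primitive erythroid from 4.74e-04 to 0.866 and intermediate mesoderm from 0.0549 to 0.844. Cell cycle ran from 0.136 to 0.9999, anterior Hox from 0.174 to 0.993, ribosomal protein from 0.220 to 0.961, closure from 0.238 to 0.958, central Hox from 0.265 to 0.998, germ cell from 0.315 to 0.961, heart from 0.356 to 0.993 and unfolded protein from 0.372 to 0.996. Retinoic acid ran from 0.428 to 0.993, hedgehog pathway from 0.434 to 0.996, endothelial from 0.441 to 0.993, Hox groups 10 to 13 from 0.638 to 0.9999, folate from 0.814 to 0.993, BMP response from 0.821 to 0.996, apoptosis from 0.844 to 0.998 and p53 targets from 0.844 to 0.996. Across all lists 470 of the alternative values kept direction and side, 29 lost a call, 21 gained it and 56 turned. The cause was not tested.

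For named genes, 1655 alternative values kept sign and side, 7 lost the call of Tm7sf3, 1 gained a call and 10 changed sign. Another probe gave the opposite sign for Ptch1 (-0.0163), Ccnt1 (0.0687) and Tbx20 (-0.0237). With an array left out the log2 difference ran from -0.0616 to 0.73 for Rspo3, -0.32 to 0.0235 for Hoxd9, -0.33 to 0.0302 for Hoxa11, -0.38 to 0.0120 for Mcm5, -0.0734 to 0.39 for Six2 and -0.0149 to 0.0539 for Cx3cr1.

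Around Fkbp8 the odds ratio of genes with a small p was 1.90 (Fisher's exact test, p = 0.415). It was 2.20 at an unadjusted p under 0.05 (Fisher's exact test, p = 0.0410), 3.64 over probes (p = 0.111), and between 0 and 17.98 with an array left out, the highest without wild-type sample 7.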

Other observations

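The tests of wild-type sample 7 around Fkbp8, of the Hox genes and of the endoderm markers were chosen only after the result was seen. The gene lists were fixed before the data were examined, and which patterns to weigh was decided with the results in view. Ret, a receptor gene of the nephric duct, had a log2 difference of 0.96 ± 0.53 (SE) that became 0.21 without null sample 9. Rpl38 had -0.71 ± 0.27 and the complex I gene Ndufa1 -0.53 ± 0.21, and each was smaller without null sample 9 (-0.36 and -0.27).

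The 6 arrays can be split into groups of 3 in 10 ways, the real split and 9 others, too few to give a share under 0.05. The real split gave 1 probe past the adjusted threshold, a number that 6 of the 10 splits, the real one included, reached, and the highest other split gave 2. It gave 7 lists, which 2 of the 10 splits, again with the real one, reached, and the highest other split gave 8. At an unadjusted p under 0.05 the real split counted 656 probes, while the others ran from 480 to 2715, most of them above 656.

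Several genes next to Fkbp8 differed between the null arrays and wild-type samples 10 and 12, and wild-type sample 7 lay nearer to the null arrays there. In the planned test over all 6 arrays, 1 of 134 genes within 10 Mb had an unadjusted p under 0.01 against 0.394% of other genes (Fisher's exact test, p = 0.415), which left a flanking strain segment open. Without sample 7, 9 of 133 genes did, against 0.402% elsewhere (Fisher's exact test, p = 9.86e-09), a value picked from 6 arrays left out in turn and over linked genes that are not independent. Zfp961 had a log2 difference of -1.12 ± 0.13 (SE) and Ccdc124 -2.02 ± 0.34 in that fit, and their signals in sample 7 (8.33 and 8.04) were those of the null group (8.32 and 8.06), not of samples 10 and 12 (9.43 and 10.1). On a scale with samples 10 and 12 at 0 and the null mean at 1, sample 7 had a mean position of 0.932 (lower 95% bound 0.730) over these genes but also a median of 0.821 over 50 genes picked the same way elsewhere, and was nearer to the nulls for 8 of 9 and 35 of 50 (Fisher's exact test, p = 0.421), so the picking may fix its place and a flanking haplotype shared with the nulls, an effect of the disrupted allele on its neighbours and a mislabelled heterozygous embryo all stay open.

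Tm7sf3 and its neighbour Fgfr1op2 were both higher in every null sample measured. Among random sets of 3 tested genes, a share of 2.0e-04 held a pair as close, so such closeness was rare among genes drawn at random. The distance was that of this pair, which was first noticed in the results. The share is therefore no independent test of a chance pairing of unrelated genes. For the size of the differences, a single array or spot is argued against. The smaller of the lowest leave-one-out ratios to the full difference was 0.904, although picking by small p favours genes with even values. A fault of a probe that recurs on every array was not tested. A strain segment that shifts many genes of the interval stays open: with the pair left out, 2 of 51 genes within 10 Mb had an unadjusted p under 0.05 against 3.20% elsewhere (Fisher's exact test, p = 0.679), and Stk38l, next to them, had 0.40 ± 0.11.

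The hedgehog response and ventral neural tube lists were placed higher in the null samples by camera at its preset correlation, and neither passed with an estimated correlation (adjusted p = 0.610 for both) or with fry (0.494). Whether a single array decides the shift of the hedgehog response list stays open. The highest unadjusted camera p over both lists and 6 arrays left out was 0.0129, for hedgehog response without wild-type sample 10. That list then missed the adjusted threshold (0.0930), with a mean log2 difference of 0.24 against 0.28 over all arrays. Other splits of the 6 arrays reached a camera p of 0.0115 for hedgehog response and 0.0114 for the ventral list. The real split gave 8.30e-05 and 8.45e-05. The ventral list passed at the preset correlation with each array left out. A more caudal cut of the null embryos stays open: the mean difference of the Hox genes of groups 10 to 13 was 0.05, but its 95% interval reached 0.256, above the 0.179 under which it had to stay to exclude such a cut, which is 0.5 times the ventral list's mean of 0.36. A different share of floor plate or of neural tube in the pieces was not tested.

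The surface ectoderm list had a highest unadjusted camera p of 2.47e-04 over the 6 arrays left out, and the endoderm markers without Epcam had a mean log2 difference of 0.01 with a lower 95% bound of -0.57, against -0.24 for the surface ectoderm, whose adjusted p was 0.543 with an estimated correlation and 0.494 with fry.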
